A study of Mus musculus with 36 samples.

How the data were processed

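RNA was measured in 24 libraries of RM-1-BM prostate cancer cells and 12 of RAW264.7 macrophages, in 12 groups of 3. The submitters' notes name TRIzol extraction of total RNA and standard Illumina library preparation. The authors deposited 1 file per library with raw read counts for 46078 genes, followed by 5 HTSeq summary lines, and no normalization had been applied. Their notes list STAR, TopHat, HTSeq and DESeq2 and genome build GRCm38, but which aligner made the counts, the versions and the strand setting are not given in the sources used here. Counts in the files were whole numbers, and none of the 36 pairs of libraries within a group was identical.

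Groups came from the labels. For 3 macrophage libraries (vector partner, olaparib) the title leaves out the partner, and the group came from the label's own group entry. The genotype entry of macrophages was not used, since it names the mutant for one F133V-partner group and wild type for the other. Replicate numbers were not used to pair libraries. Gene counts per library ranged from 32063028 to 43062440 in cancer cells (median 37771351) and from 30292309 to 37340425 in macrophages (median 35333491). Of all counted reads, 17.2% to 21.5% fell in no gene, 1.2% to 1.36% were ambiguous and 5.48% to 7.18% did not align uniquely. Between 19009 and 21038 genes had a count.

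Each cell type was fitted on its own in edgeR 4.0.16 under R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10 and the quasi-likelihood F test. That left 15962 genes in cancer cells (8 groups, 16 residual degrees of freedom, common biological coefficient of variation 2.61%) and 14262 in macrophages (4 groups, 8 degrees of freedom, 1.81%). TMM factors ran from 0.849 to 1.056 and from 0.951 to 1.053. There were 17 comparisons: 12 between 2 groups and 5 interactions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The SE of a log2 fold change was its size divided by the square root of F. The 30 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation; 203 list tests passed with the preset and 137 with the estimate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

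The groups, comparisons, lists, rule for naming genes and the alternatives up to leaving out libraries were chosen before the data were examined. The text names genes from a fixed set (among them Spop, Parp1, Parp2, Parp3, Sting1, Cgas, Ifnb1, Stat3, Il6, Tnf, Ccl2, Ccl5, Cxcl10, Cd274, Csf1, Cdkn1a and Myc). To these it adds, per comparison of 2 groups, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out model names. It further adds up to 4 members per list with the smallest adjusted p among those called (up to 2 others where fewer than 2 are) and, per interaction, the 6 called genes with the smallest adjusted p, and it names fewer than these allow. Lyz2 was shown as a marker of macrophages and was chosen for its level.

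The procedure was tested on simulated data, with 50 genes changed at each fold. Rises and falls were equal in number and genes varied independently. Real contrasts were far broader (10809 of 15962 genes called for F133V against vector monoculture), so these shares need not carry over to them. For F133V against vector monoculture (15457 genes) it called 78% of genes changed 1.2-fold, 86% at 1.5-fold, 96% at 2-fold and 100% at 3-fold, and 2.7% of its calls were false. For the interaction of genotype and olaparib in monoculture (15449 genes) the shares were 58%, 74%, 96% and 98%, with 5.8% false. For the macrophage partner with DMSO (14079 genes) they were 68%, 92%, 98% and 100%, with 3.8% false, and for the macrophage interaction (14088 genes) 54%, 82%, 96% and 100%, with 6.2% false. A list of 30 genes shifted 1.2-fold was called in both cell types. Its genes were simulated without correlation, so this does not test how correlated genes affect list calls.

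Alternatives tried were DESeq2 1.42.0, RLE scaling, scaling by library size alone, no filter on low counts, only the groups of a comparison, a replicate block, each library left out in turn, protein-coding genes only, the removal of 2 vector libraries with macrophage transcripts, and the removal of trends on gene length and GC content. Length and GC came from GENCODE M21 and were known for 99.4% and 99.5% of tested genes. No library was left out of the reported values. Without a known strand setting, counts of genes whose exons overlap another gene are uncertain. This holds for 33 of the 97 named genes: Bcl3, Bhlhe40, Bhlhe41, Bnip3, Brca2, Brd2, Ccnd1, Cd274, Cdkn1a, Cebpd, Col3a1, Csf1r, Ctsa, Ddit3, Dsp, Fn1, Gclm, Hexa, Irf1, Krt8, Lss, Ndrg1, Parp1, Parp3, Pdia4, Prc1, Rad54l, Slc2a1, Sqstm1, Stat3, Tapbp, Top2a and Vcam1.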

Results

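RNA was sequenced from 2 mouse cell types. RM-1-BM is a prostate cancer cell line that carried either an empty vector or the F133V mutant of SPOP, the substrate adaptor of a ubiquitin ligase that is often mutated in prostate cancer. RAW264.7 is a macrophage line. Cancer cells were grown alone or opposite macrophages in a transwell, where the 2 cell types share medium through a membrane. Each culture received olaparib, an inhibitor of PARP enzymes, or the vehicle DMSO. The 36 libraries form 12 groups of 3: 8 groups of cancer cells (vector or F133V, alone or in coculture, DMSO or olaparib) and 4 groups of macrophages, each taken from a coculture. No macrophage grown alone is in the series, so a change in macrophages is always relative to another coculture. Gene counts per library ranged from 30292309 to 43062440, with a median of 36623720. Values below are edgeR CPM (counts scaled by library size with TMM), mean ± SD of 3 libraries, and log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. List members not given as higher or lower were not called. An interaction is the log2 change in F133V cells, or with the F133V partner, minus that in vector cells, so a negative one can be a smaller rise or a larger fall. The labels do not say whether the 3 libraries of a group came from separate cultures, and the p-values measure only the spread between these libraries.

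Spop (chromosome 11, 95414080 to 95493406, plus strand, GRCm38) was measured first, since it is the transduced gene. In monoculture with DMSO it read 106 ± 1.57 CPM in F133V cells and 117 ± 2.65 in vector cells (log2 fold change −0.15 ± 0.03, adjusted p = 7.2e-05). In coculture it read 96.8 ± 2.91 and 125 ± 1.88 CPM (−0.36 ± 0.03, adjusted p = 2.8e-13). The total for Spop was thus slightly lower in F133V cells, and whether reads from the introduced construct were counted for it is not given in the sources used here. With gene length and GC trends removed, the monoculture difference was −0.01 and was not called. The genotype labels were therefore not checked by the mutant allele itself. The first principal component of the cancer libraries held 57.8% of the variance and put all 12 vector libraries on one side and all 12 F133V libraries on the other.

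F133V cells also differed in structural RNA, the genes annotated as small nuclear, Cajal body, ribozyme or miscellaneous RNA. These took 370 ± 12 CPM of gene counts in F133V monoculture with DMSO against 67 ± 2 in vector cells, and 409 ± 14 against 66.5 ± 2.1 in coculture. With olaparib the F133V values were 187 ± 13 alone and 100 ± 2.7 in coculture, and vector cells read 62.2 ± 2.3 and 57.7 ± 1.1. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, led this class. It read 188 ± 0.716 CPM in F133V and 9 ± 0.672 in vector monoculture (4.38 ± 0.05, adjusted p = 7.2e-41). Outside this class, Gm26917, chosen after its values were seen, took 3.84 ± 0.08% of gene counts in F133V and 0.2% in vector monoculture with DMSO, and 3.56 ± 0.09% against 0.26% in coculture. With olaparib it took 1.43 ± 0.17% in F133V monoculture and 0.49 ± 0.01% in coculture, and 0.16% and 0.18% in vector cells. The mitochondrial ribosomal RNA mt-Rnr2 read 4200 ± 90.6 CPM in F133V and 994 ± 91.9 in vector monoculture (2.08 ± 0.05, adjusted p = 7.8e-30), and 5020 ± 191 against 1040 ± 56.7 in coculture (2.27 ± 0.05). With olaparib it read 2750 ± 339 in F133V monoculture and 1230 ± 33.5 in coculture. Most mitochondrially encoded genes did not rise with it. In F133V against vector monoculture with DMSO, 14 of 24 were lower and 2 higher (median −0.39, 13 lower adjusted over the list alone). In coculture 13 were lower and 4 higher (median −0.55), and camera called neither (adjusted p = 0.93 and 0.63). With olaparib 16 of the 24 were higher and 2 lower in F133V monoculture, and 7 higher and 4 lower in F133V coculture. These measured differences accompany the contrasts of genotype in cancer cells below, and the olaparib contrasts within F133V cells.

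**Figure D1:**
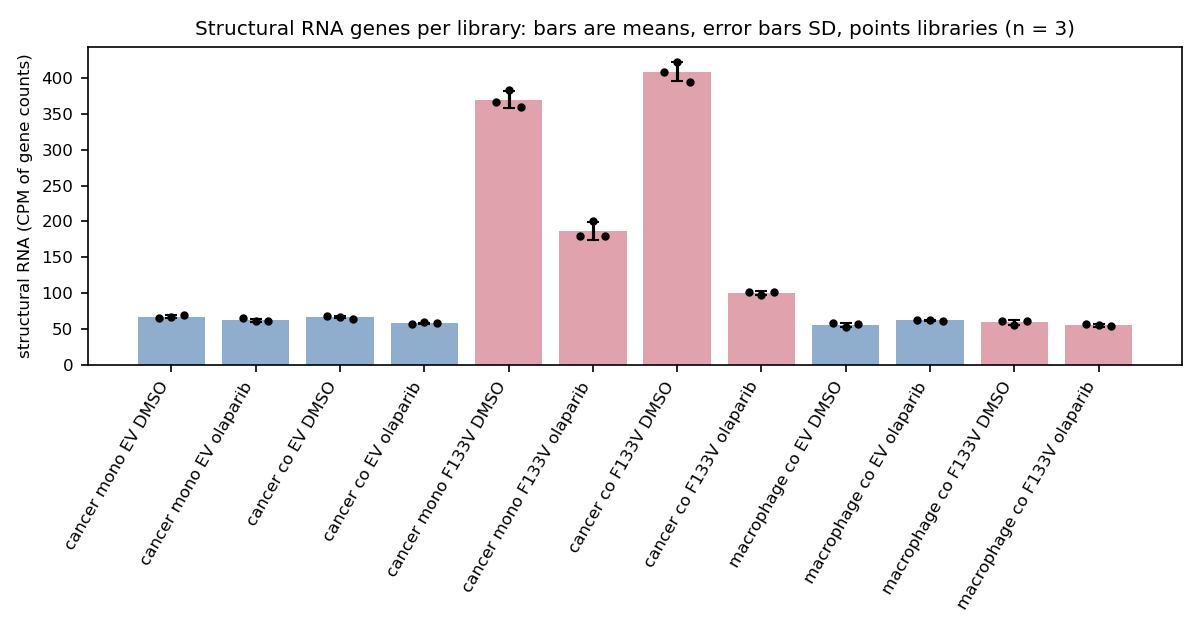
Structural RNA genes per library, as CPM of gene counts, for the 8 cancer and 4 macrophage groups; bars are means, error bars SD and points the 3 libraries. F133V cancer cells with DMSO average 370 alone and 409 in coculture, against 66.5 to 67 in vector cells and 55.1 to 61.9 in macrophages.

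The first comparison asks how F133V cells differed from vector cells, grown alone with DMSO. It cannot separate the mutant from other differences between the vector and F133V cells, and this holds for all contrasts of genotype below. F133V cells had much less sterol synthesis, glycolysis and cell division message, and more message for antioxidant and stress proteins. All 25 measured genes of sterol synthesis were lower (median log2 fold change −1.83). Among hypoxia and glycolysis genes, 33 of 34 were lower and 1 higher (median −0.92). Egln3, an oxygen-sensing prolyl hydroxylase, fell from 448 ± 3.86 to 70.8 ± 1.75 CPM, and Slc2a1, the glucose transporter GLUT1, from 1070 ± 8.09 to 364 ± 6.38.

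Mitosis genes were lower in 36 of 37 cases (median −1.03) and S phase genes in 31 of 37, with 2 higher (median −0.65). Mki67, the proliferation antigen Ki-67, changed by −1.73 ± 0.04 and Top2a, a topoisomerase of dividing cells, by −1.08 ± 0.03. Among genes of homologous recombination, the pathway whose loss sensitizes cells to PARP inhibitors, 33 of 49 were lower and 5 higher (median −0.35). Brca1 fell from 17.7 ± 0.552 to 9.04 ± 0.924 CPM (adjusted p = 3.2e-17), and Rad54l changed by −1.73 ± 0.11. This list's adjusted p of 0.031 in limma's camera became adjusted p = 0.14 with an estimated correlation. NRF2 target and antioxidant genes were higher in 18 of 22 cases and lower in 4 (median 0.83). Gclm, a subunit of the enzyme that makes glutathione's precursor (chromosome 3, 122245557 to 122270732), rose from 26.8 ± 0.373 to 123 ± 2.9 CPM, and Txnrd1, thioredoxin reductase, by 1.54 ± 0.02. Genes of the integrated stress and unfolded protein responses were higher in 25 of 29 cases and lower in 1 (median 0.52). Hspa5, the main chaperone of the endoplasmic reticulum, rose by 1.31 ± 0.02 and Slc7a11, the cystine importer, by 1.86 ± 0.03.

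Single genes moved further. Myc, the growth-promoting transcription factor, rose from 19.3 ± 1.3 to 145 ± 5.54 CPM (2.90 ± 0.05, adjusted p = 7.7e-36), and Csf1, the growth factor of macrophages, from 76.9 ± 2.78 to 328 ± 2.5 (2.09 ± 0.03, adjusted p = 2.5e-39). Ptgs2, the cyclooxygenase COX-2, rose by 2.14 ± 0.03. Col3a1, a fibrillar collagen, fell from 640 ± 8.99 to 51.8 ± 1.11 CPM and Fn1, fibronectin, from 8100 ± 84.4 to 2150 ± 15.4. The matrix list as a whole went both ways (12 higher, 14 lower of 29, with Bgn up by 1.63 ± 0.02): its median was 0.08, or −0.01 when scaled by library size alone, while its mean was −0.38 and camera's direction was down (adjusted p = 1.7e-04). Keratin 8 (Krt8) was nearly lost, at 0.352 ± 0.15 against 22.9 ± 0.94 CPM, and 6 of 11 epithelial and prostate genes were lower with 1 higher (median −1.17). Stat3 changed by −0.80 ± 0.03, Parp1 by −0.32 ± 0.03 and Cdkn1a by −0.43 ± 0.02. Of 15962 genes tested, 10809 were called, 5378 higher and 5431 lower, 2536 of them at least 2-fold. The higher share was 49.8%, or 40.5% scaled by library size alone. All these lists passed camera, at adjusted p = 1.6e-51 for sterol synthesis, 2.5e-48 for hypoxia and 1.5e-17 for mitosis. Apart from homologous recombination they kept the call with an estimated correlation, and their counts were the same adjusted over the list alone. Macrophage lineage genes were lower in 10 of 14 cases (median −1.07, camera adjusted p = 0.44), and 2 of the 3 vector libraries held macrophage transcripts.

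In coculture the same contrast shows how F133V cells differed from vector cells opposite macrophages. The antioxidant difference was large. Gclm stood at 339 ± 12.2 CPM in F133V and 26.3 ± 0.866 in vector cells (3.69 ± 0.03, adjusted p = 2.4e-44), Txnrd1 at 1880 ± 33.2 and 255 ± 2.63, and Slc7a11 at 2070 ± 40.8 and 314 ± 8.74. NRF2 genes were higher in 19 of 22 cases and lower in 2 (median 1.34). Interferon-stimulated genes were lower in 37 of 42 cases and higher in 2 (median −1.79). Stat2, which carries the interferon signal, changed by −1.40 ± 0.04. Oas3, which activates RNase L, changed by −5.24 ± 0.16 and Ddx58, the RNA sensor RIG-I, by −1.5 ± 0.05. MHC class I and antigen processing genes were lower in 11 of 14 cases and higher in 2 (median −1.17, camera adjusted p = 0.0082). That call was lost with an estimated correlation (adjusted p = 0.11), and H2-K1 (−1.23 ± 0.03) shares sequence with other class I genes, so its counts are uncertain.

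Sterol synthesis was lower in all 25 genes (median −1.57), with Insig1, a sterol sensor, at −2.17 ± 0.03. All 37 mitosis genes were lower (median −0.95), among them Mki67 at −1.66 ± 0.04 and Cenpf, a kinetochore protein, at −1.37 ± 0.03. Hypoxia and glycolysis genes were lower in 25 of 34 cases and higher in 6 (median −0.53): Egln3 changed by −1.87 ± 0.03, whereas Kdm3a, a histone demethylase, rose by 1.57 ± 0.03. Homologous recombination genes were lower in 34 of 49 cases and higher in 10 (median −0.72, camera adjusted p = 0.038, adjusted p = 0.12 with an estimated correlation), with 11 higher adjusted over the list alone and Brca2 at −1.79 ± 0.07. Krt18, keratin 18, stood at 370 ± 13.7 against 78.4 ± 1.06 CPM and Dsp, desmoplakin of cell junctions, at 69.5 ± 2.06 against 11.6 ± 0.201. The epithelial and prostate list went both ways, however (5 higher, 6 lower of 11, median −0.27), and did not pass camera (adjusted p = 0.74). Fgfr4, a growth factor receptor, read 14 ± 0.811 against 0.0787 ± 0.0524 CPM. Ptgs2 rose by 2.77 ± 0.03, Myc by 1.80 ± 0.05, Csf1 by 0.65 ± 0.03 and Cd274, the checkpoint ligand PD-L1, by 0.67 ± 0.08, while Ccl2, a monocyte attractant, changed by −2.19 ± 0.12. A total of 12686 genes were called, 5975 higher and 6711 lower (47.1% higher), or 34.7% higher when scaled by library size alone, and 5005 moved at least 2-fold. Camera's adjusted p was 1.2e-27 for NRF2, 2.6e-21 for sterol synthesis, 1.8e-09 for mitosis, 1.7e-04 for interferon and 9.4e-07 for hypoxia. These calls held with an estimated correlation, and the counts were the same adjusted over the list alone except for homologous recombination. Scaling by library size alone shifted the median of all genes by −0.253 here.

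**Figure D2:**
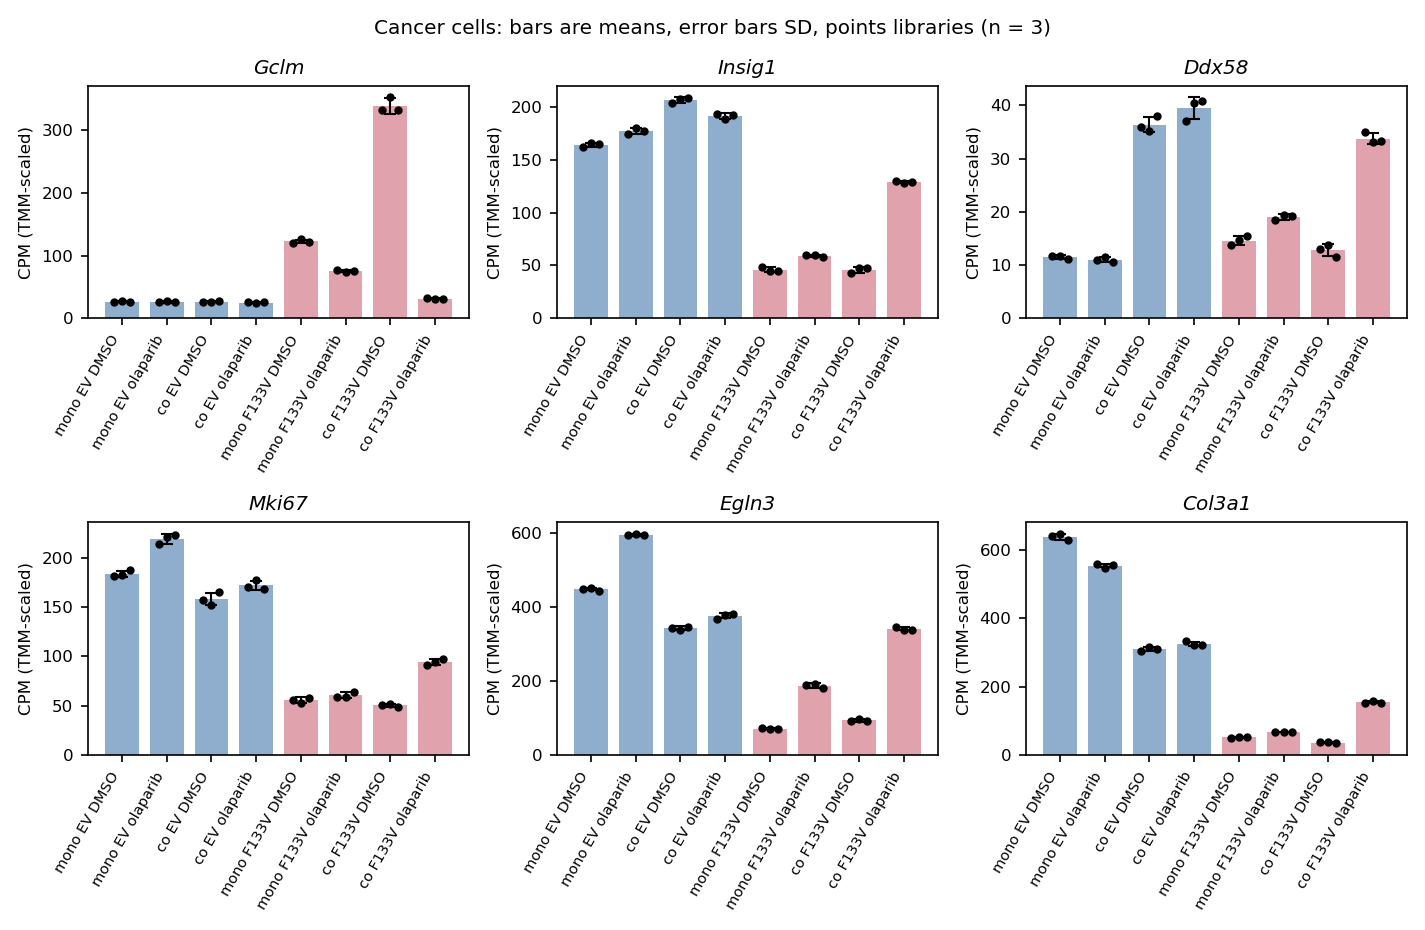
TMM-scaled CPM of 6 genes in the 8 groups of cancer cells; bars are means, error bars SD and points the 3 libraries, with vector cells in blue and F133V cells in red. Gclm averages 339 in F133V coculture with DMSO and 31.2 with olaparib, and 26.3 in vector coculture with DMSO.

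Coculture against monoculture, both with DMSO, asks what the presence of macrophages changed in cancer cells. In vector cells the response was inflammatory. NF-kB target and inflammatory genes were higher in 25 of 27 cases (median 0.79), interferon-stimulated genes in 34 of 42 with 1 lower (median 0.87), and MHC class I genes in 12 of 14 (median 0.54). Ccl2 rose from 2.76 ± 0.0882 to 9.44 ± 0.446 CPM (1.77 ± 0.11, adjusted p = 1.7e-16) and Ddx58 from 11.5 ± 0.347 to 36.4 ± 1.38 (1.66 ± 0.05, adjusted p = 2.5e-25). Bst2, which tethers budding viruses, rose by 1.64 ± 0.07, Cebpd, an inflammatory transcription factor, by 1.37 ± 0.05, Ptgs2 by 0.91 ± 0.03, Vcam1, an adhesion molecule for leukocytes, by 1.06 ± 0.03 and B2m, the light chain of MHC class I, by 0.61 ± 0.03. Csf1 rose by 0.58 ± 0.03 and Cd274 by 0.57 ± 0.08. Stress and unfolded protein response genes were higher in 20 of 29 cases and lower in 5 (median 0.24), led by Calr, calreticulin, from 617 ± 7.99 to 1670 ± 2.34 CPM and by Hspa5 (1.14 ± 0.02). STAT3 targets were higher in 15 of 21 cases and lower in 4 (median 0.19), with Bcl3 up by 1.85 ± 0.09, and NRF2 genes in 13 of 22 with 3 lower (median 0.14, camera adjusted p = 5.8e-06).

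Other lists fell in these vector cells. Mitosis genes were lower in 27 of 37 cases and higher in 1 (median −0.23; 31 lower adjusted over the list alone), with Top2a at −0.24 ± 0.03, while S phase genes were not called as a list (8 higher, 5 lower of 37, camera adjusted p = 0.66). Matrix genes were lower in 13 of 29 cases and higher in 5 (15 lower adjusted over the list alone): Col3a1 fell from 640 ± 8.99 to 310 ± 4.98 CPM and Fn1 by 0.93 on the log2 scale. Immediate early genes were lower in 16 of 23 cases and higher in 3 (17 lower adjusted over the list alone), with Egr1 at −1.09 ± 0.07. Abca1, which exports cholesterol from cells, changed by −2.06 ± 0.06. Counts of the other lists named for these vector cells were the same adjusted over the list alone. For the lists named here as called, camera's adjusted p ran from 3.8e-49 (stress) and 9.5e-23 (interferon) to 1.5e-04 (immediate early genes). These lists held with an estimated correlation. Called lists not named here lost the call with it: p53 targets (camera adjusted p of 0.014 became 0.14) and lysosome genes (0.0048 became 0.2). The list of classical macrophage activation lost it too (0.016 became 0.075). In total 6710 genes were called, 3736 higher and 2974 lower (55.7% higher), or 42.2% higher scaled by library size alone. At least 2-fold changes were called in 477 genes, 177 higher and 300 lower. In 2 of the 3 vector monoculture libraries with DMSO, Lyz2, a lysozyme abundant in macrophages, read 3.6 and 4.6 CPM against 0.7 in the other, and macrophages themselves averaged 3660 to 4670.

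In F133V cells the same step into coculture raised antioxidant and glycolysis genes. NRF2 genes were higher in 19 of 22 cases and lower in 2 (median 0.90): Txnrd1 rose from 711 ± 0.976 to 1880 ± 33.2 CPM (1.40 ± 0.02, adjusted p = 3.5e-37) and Gclm by 1.47 ± 0.03. Hypoxia and glycolysis genes were higher in 29 of 34 cases and lower in 3 (median 0.58), with Kdm3a up by 1.5 ± 0.03 and Slc2a1 by 1.25 ± 0.02. Krt18 rose from 97.4 ± 1.54 to 370 ± 13.7 CPM, and epithelial genes were higher in 8 of 11 cases and lower in 1 (median 0.62, camera adjusted p = 0.015, adjusted p = 0.10 with an estimated correlation). Interferon genes were not called as a list (5 higher, 16 lower of 42, camera adjusted p = 0.64), and Csf1 changed by −0.86 ± 0.03. Ptgs2 rose by 1.54 ± 0.03 and Ier3, an early response gene, by 2.20 ± 0.04, while Ccnd1, cyclin D1, fell from 275 ± 4.63 to 94.8 ± 3.55 CPM. Ptgs2 and Ier3 are in the NF-kB and inflammatory list, which was not called here (14 higher, 9 lower of 27, camera adjusted p = 0.24). Nor was MHC class I (6 higher, 6 lower of 14, camera adjusted p = 0.87). Mitosis genes were lower in 29 of 37 cases and higher in 1 (median −0.30, camera adjusted p = 0.013, adjusted p = 0.067 with an estimated correlation), and S phase genes were not called as a list (16 higher, 11 lower of 37, camera adjusted p = 0.87). Stress genes were higher in 22 of 29 cases and lower in 5 (median 0.30, camera adjusted p = 5.9e-04, adjusted p = 0.37 with an estimated correlation; not called scaled by library size alone). Here 11226 genes were called, 5677 higher and 5549 lower (50.6% higher), or 34.6% higher scaled by library size alone, which shifted the median of all genes by −0.209. The lists for NRF2 (adjusted p = 1.6e-23) and hypoxia (4.9e-16) kept their call with an estimated correlation, with the same counts adjusted over the list alone, apart from the interferon list (15 lower) and S phase (17 higher).

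The difference between these 2 responses was tested as the interaction of genotype and coculture, which called 10008 genes, 4814 higher and 5194 lower in F133V cells (48.1% higher, or 35.7% scaled by library size alone, with a median shift of −0.162). Interferon genes had a negative interaction in 29 of 42 cases (median −1.21, adjusted p = 1.4e-04), with Ddx58 at −1.84 ± 0.08 (adjusted p = 2.8e-21). NRF2 genes had a positive interaction in 15 of 22 cases and negative in 3 (median 0.73), hypoxia genes positive in 27 of 34 and negative in 4 (median 0.44) and epithelial genes positive in 6 of 11 (median 0.57). Txnrd1 differed by 1.34 ± 0.03, Krt18 by 2.27 ± 0.05, Csf1 by −1.44 ± 0.04 and Cebpd by −1.79 ± 0.10. These 4 lists held with an estimated correlation, and their counts were the same adjusted over the list alone. NF-kB and inflammatory genes had a negative interaction in 16 of 27 cases and positive in 5 (median −0.46). MHC class I genes were negative in 10 of 14 and positive in 1 (median −1.10). Their camera adjusted p of 0.036 and 0.0051 became 0.091 for both lists with an estimated correlation. Macrophage lineage genes had a positive interaction in 8 of 14 cases and negative in 2 (median 1.76, camera adjusted p = 0.41). The vector monoculture libraries with macrophage transcripts enter this contrast.

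Olaparib against DMSO asks how cells responded to the drug. In vector cells grown alone the changes were small. All 37 mitosis genes were higher (median 0.34), S phase genes in 33 of 37 cases (median 0.31; 1 lower adjusted over the list alone), and homologous recombination genes in 28 of 49 with 1 lower (median 0.19). Cenpf rose from 97.9 ± 0.218 to 145 ± 2.38 CPM (0.57 ± 0.03, adjusted p = 1.4e-18), Rrm2, a subunit of ribonucleotide reductase, by 0.57 ± 0.03, Rad54l by 0.64 ± 0.08 and Brca1 by 0.47 ± 0.05. Parp1, a target of the drug, rose by 0.13 ± 0.03 and Cdkn1a, the cell cycle inhibitor p21, by 0.12 ± 0.02. Hypoxia genes were higher in 28 of 34 cases and lower in 2 (30 higher adjusted over the list alone), with Slc2a3, the glucose transporter GLUT3, up by 0.67 ± 0.03. Sterol synthesis genes were higher in 21 of 25 cases (median 0.20). Stress genes were lower in 21 of 29 cases and higher in 1 (median −0.27), including Ddit3, the stress factor CHOP, from 320 ± 1.38 to 204 ± 2.42 CPM and Atf3 (−0.77 ± 0.04). Ptgds, a prostaglandin D synthase, rose from 1.4 ± 0.0589 to 7.45 ± 0.169 CPM and Abca1 by 1.3 ± 0.05, while Myc changed by −0.89 ± 0.07. Of the genes tested, 4857 were called, 2445 higher and 2412 lower (50.3% higher), or 40.9% higher scaled by library size alone, and 145 moved at least 2-fold. Without the pair of vector DMSO libraries that held macrophage transcripts, 2952 were called. The 6 lists had camera adjusted p between 5e-30 and 1.6e-05 and held with an estimated correlation, with the same counts adjusted over the list alone except for hypoxia and S phase. Macrophage lineage genes were lower in 9 of 14 cases and higher in 1 (median −1.68, camera adjusted p = 0.078), and 2 of the 3 control libraries held such transcripts.

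In F133V cells grown alone, olaparib raised glycolysis genes. Hypoxia and glycolysis genes were higher in 25 of 34 cases and lower in 1 (median 0.41): Egln3 rose from 70.8 ± 1.75 to 187 ± 5.99 CPM (1.40 ± 0.03, adjusted p = 1.5e-31), Slc2a3 by 1.3 ± 0.03 and Hk2, hexokinase 2, by 0.77 ± 0.02. Bhlhe40, a repressor induced by low oxygen, rose from 47.6 ± 2.12 to 161 ± 1.3 CPM and Apln, the vascular peptide apelin, by 1.62 ± 0.06. Interferon genes were higher in 18 of 42 cases and lower in 1 (median 0.38), with Stat2 at 0.31 ± 0.05 and Irf1 at 0.37 ± 0.04. Sterol synthesis genes were higher in 16 of 25 cases (17 adjusted over the list alone) and lower in 1 (median 0.24), and lysosome genes in 19 of 21 with 1 lower (median 0.19), with Ctsa, a lysosomal protease, at 0.38 ± 0.02. NRF2 genes were lower in 15 of 22 cases and higher in 2 (median −0.15): Gclm changed by −0.71 ± 0.03. Akr1b3, aldose reductase, fell from 260 ± 3.44 to 104 ± 4.32 CPM. Of 77 ribosomal protein genes, which share sequence with many pseudogenes and are uncertain one by one, 76 were lower (median −0.21). Rn7sk fell from 188 ± 0.716 to 76.2 ± 5.5 CPM. Parp1 was not called (−0.04 ± 0.03, adjusted p = 0.34; 0.04 scaled by library size alone). Altogether 5772 genes were called, 2912 higher and 2860 lower (50.5% higher), or 74.6% higher scaled by library size alone, and 317 moved at least 2-fold. Camera's adjusted p ran from 6.6e-66 for hypoxia to 0.0036 for interferon, and these lists held with an estimated correlation, with the same counts adjusted over the list alone except for sterol synthesis.

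The interaction of genotype and olaparib in monoculture called 3867 genes, 2122 higher and 1745 lower in F133V cells (54.9% higher, or 82.7% scaled by library size alone). Of 30 random splits of the 12 libraries, the real one included, 2 called as many genes, and the other one lined up fully with genotype. S phase genes had a negative interaction in 31 of 37 cases (median −0.39), mitosis genes negative in 26 of 37 (31 adjusted over the list alone) (median −0.25), and homologous recombination genes negative in 19 of 49 (20 adjusted over the list alone) and positive in 1 (median −0.17). Hypoxia genes had a positive interaction in 18 of 34 cases and negative in 2 (median 0.13), with Bhlhe40 at 1.08 ± 0.04 and Egln3 at 0.99 ± 0.04, and Akr1b3 differed by −0.95 ± 0.04 (adjusted p = 3.9e-20). These 4 lists passed camera at adjusted p between 1.2e-19 and 8.7e-05 and held with an estimated correlation.

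In vector cancer cells in coculture with macrophages, olaparib moved few genes far. Stress genes were lower in 28 of 29 cases (median −0.25), with Hspa5 from 2370 ± 53.9 to 1760 ± 16.3 CPM (−0.43 ± 0.02, adjusted p = 1.7e-18), Slc7a11 at −0.51 ± 0.03 and Ddit3 at −0.40 ± 0.02. Lysosome genes were higher in 18 of 21 cases (19 adjusted over the list alone) and lower in 1 (median 0.16), with Hexa at 0.28 ± 0.02. Mitosis genes were higher in 17 of 37 cases (median 0.12), and MHC class I genes in 7 of 14 with 1 lower (median 0.18), with Tapbp, which loads peptides onto MHC class I, at 0.39 ± 0.03. Ptgds rose from 2.13 ± 0.33 to 16 ± 0.0702 CPM, Serpina3n, a protease inhibitor of the acute phase, from 11.4 ± 1 to 38.1 ± 1.38 and Abca1 by 1.72 ± 0.07, while Krt19 changed by −0.82 ± 0.06 and Cd274 by −0.42 ± 0.08. Altogether 3765 genes were called, 2019 higher and 1746 lower, and 125 moved at least 2-fold. These 4 lists passed camera at adjusted p of 8e-49, 1.4e-14, 8e-05 and 4.5e-04 in that order and held with an estimated correlation. NRF2 genes were lower in 13 of 22 cases and higher in 2 (median −0.12). Their camera adjusted p of 7.4e-05 became 0.052 with an estimated correlation. Hypoxia genes were lower in 16 of 34 cases and higher in 4 (17 and 5 adjusted over the list alone; median −0.07). Their camera adjusted p of 0.0027 became 0.17.

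In F133V cancer cells in coculture with macrophages, olaparib changed 12185 genes, 6280 higher and 5905 lower, 4024 of them at least 2-fold. The antioxidant genes fell: NRF2 genes were lower in 19 of 22 cases and higher in 2 (median −1.02), with Gclm from 339 ± 12.2 to 31.2 ± 0.505 CPM (−3.44 ± 0.03, adjusted p = 7.4e-44), Txnrd1 from 1880 ± 33.2 to 348 ± 4.68, and Osgin1 at −3.93 ± 0.06. Interferon genes rose in 35 of 42 cases and fell in 1 (median 1.39). Ddx58 rose by 1.39 ± 0.05 and Ifi204, a DNA sensor, by 1.62 ± 0.05. Sterol synthesis genes were higher in 23 of 25 cases and lower in 1 (median 1.26), with Insig1 at 1.49 ± 0.03 and Lss at 1.53 ± 0.03. Hypoxia and glycolysis genes were higher in 27 of 34 cases and lower in 4 (median 0.70), with Egln3 at 1.87 ± 0.03 and Slc2a3 at 1.81 ± 0.03. All 37 mitosis genes were higher (median 0.81), with Cenpf from 35.9 ± 2.51 to 98.7 ± 0.858 CPM and Top2a at 0.90 ± 0.03. S phase genes went both ways and did not pass camera (13 higher, 19 lower of 37, median −0.11, adjusted p = 0.69).

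The p53 targets were lower in 25 of 35 cases and higher in 6 in these F133V cocultures (median −0.46): Gdf15, a stress cytokine, changed by −2.07 ± 0.04, Eda2r, a death receptor, by −2.05 ± 0.04 and Cdkn1a by −0.64 ± 0.02. Col3a1 rose from 35.7 ± 1.32 to 155 ± 3.5 CPM, Fn1 by 1.42 ± 0.02, Parp1 by 0.52 ± 0.03 and Parp3 by 1.38 ± 0.04. The matrix list went both ways (14 higher, 11 lower of 29, median 0.26). Its camera adjusted p of 0.0077 became 0.11 with an estimated correlation. Selenbp1, a selenium-binding protein, rose from 0.81 ± 0.206 to 17.6 ± 0.281 CPM, and Fgfr4 fell from 14 ± 0.811 to 0.0997 ± 0.111. All 6 lists other than S phase and matrix passed camera, from adjusted p = 5.9e-22 for NRF2 to 1.1e-04 for interferon, and held with an estimated correlation, with the same counts adjusted over the list alone. The higher share of calls was 51.5%, or 63.5% scaled by library size alone, which shifted the median of all genes by 0.207. Structural RNA fell from 409 ± 14 to 100 ± 2.7 CPM alongside.

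The interaction of genotype and olaparib in coculture called 10751 genes, 5651 higher and 5100 lower in F133V cells (52.6% higher, or 65.9% scaled by library size alone, with a median shift of 0.204). Interferon genes had a positive interaction in 32 of 42 cases (median 1.28), sterol synthesis genes positive in 23 of 25 and negative in 1 (median 1.28), hypoxia genes positive in 27 of 34 and negative in 3 (median 0.77) and mitosis genes positive in 36 of 37 (median 0.67), while S phase genes were positive in 9 of 37 and negative in 18 (median −0.17, camera adjusted p = 0.43). NRF2 genes had a negative interaction in 17 of 22 cases and positive in 3 (median −0.88), and p53 targets negative in 26 of 35 and positive in 4 (median −0.54). The difference was −3.38 ± 0.05 for Gclm (adjusted p = 1.2e-35), −3.39 ± 0.04 for Akr1b3, 1.27 ± 0.07 for Ddx58 and 1.27 ± 0.05 for Cenpf. The interaction of coculture and olaparib, the change with olaparib in coculture minus that in monoculture averaged over genotypes, called 8957 genes, 4680 higher and 4277 lower (52.2% higher, or 65.0% scaled by library size alone). In it NRF2 genes were lower in 17 of 22 cases and higher in 2 (3 adjusted over the list alone; median −0.48), interferon genes higher in 26 of 42 and lower in 1 (median 0.51) and sterol genes higher in 19 of 25 and lower in 3 (median 0.38). Gclm differed by −1.38 ± 0.04, Col3a1 by 1.01 ± 0.03 and Ddx58 by 0.60 ± 0.06 (adjusted p = 9.4e-12). For the genes and lists named for this last interaction, the average describes neither genotype. With olaparib, Gclm went from 26.8 to 26.1 CPM alone and from 26.3 to 25.1 in coculture in vector cells, and from 123 to 75.1 and from 339 to 31.2 in F133V cells. The interferon medians for olaparib were 0.14 alone and 0.12 in coculture in vector cells, and 0.38 and 1.39 in F133V cells. For sterol synthesis the medians were 0.20 alone and −0.07 in coculture in vector cells, and 0.24 and 1.26 in F133V cells. For NRF2 they were −0.01 and −0.12 in vector cells, and −0.15 and −1.02 in F133V cells. Apart from S phase, each list named for these 2 interactions passed camera (largest adjusted p = 0.015) and held with an estimated correlation.

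**Figure D3:**
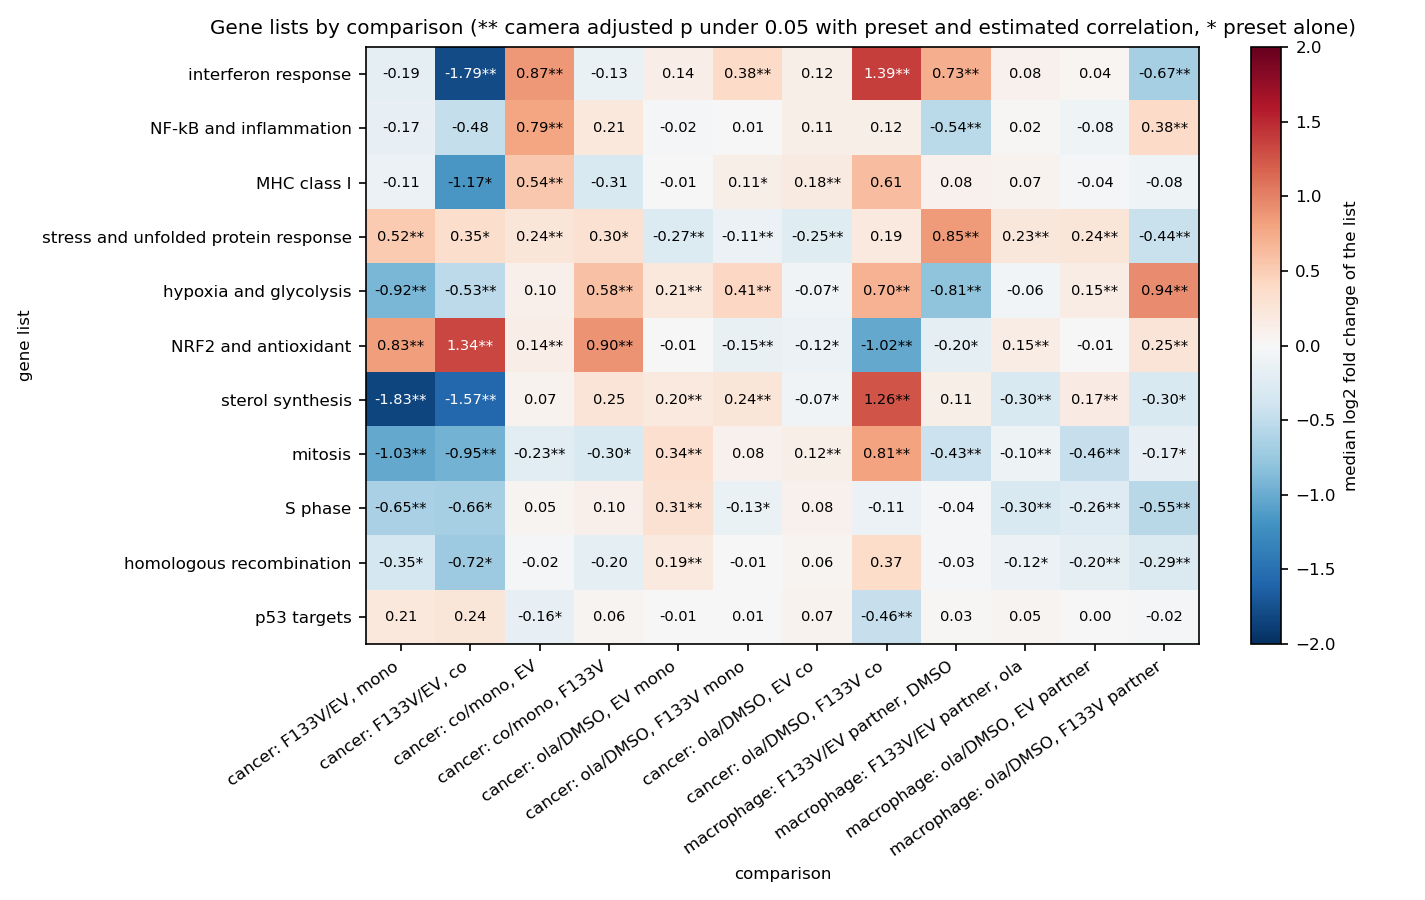
Median log2 fold change of 11 gene lists (vertical axis) in the 12 comparisons of 2 groups (horizontal axis), with the colour scale from −2 to 2; * marks camera adjusted p under 0.05 with the preset correlation and ** with the estimated one as well. Sterol synthesis stands at −1.83 and −1.57 for F133V against vector cells, and at 1.26 for olaparib in F133V coculture.

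Macrophages opposite F133V cells were compared with macrophages opposite vector cells, both with DMSO, to show how they differed by partner. Glycolysis, inflammatory and mitosis genes were lower, and interferon and stress response genes higher, while S phase genes (9 higher and 12 lower of 37, or 13 lower adjusted over the list alone; median −0.04) did not pass camera (adjusted p = 0.83). Hypoxia and glycolysis genes were lower in 32 of 34 cases and higher in 2 (median −0.81): Bnip3, a mitophagy receptor induced by low oxygen (chromosome 7, 138890836 to 138909519), fell from 397 ± 1.96 to 111 ± 3.12 CPM (−1.84 ± 0.02, adjusted p = 1.7e-52), Slc16a3, the lactate exporter, changed by −1.26 ± 0.02 and Vegfa, the vascular growth factor, by −0.76 ± 0.02. Stress and unfolded protein response genes were higher in 25 of 28 cases and lower in 2 (median 0.85), with Pdia4, a disulfide isomerase, from 289 ± 4.14 to 942 ± 6.05 CPM (1.70 ± 0.02, adjusted p = 8e-54), Creld2 at 1.77 ± 0.02 and Hspa5 at 1.10 ± 0.01. Interferon genes were higher in 40 of 46 cases (median 0.73), with Ifi44 from 17.3 ± 0.814 to 59.9 ± 0.807 CPM, Oas2 at 1.05 ± 0.03 and Ddx58 at 0.88 ± 0.05.

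NF-kB and inflammatory genes were lower in 25 of 30 cases and higher in 3 in these macrophages (median −0.54). Tnf, the inflammatory cytokine, fell from 58.8 ± 2.25 to 34 ± 0.427 CPM (−0.79 ± 0.04, adjusted p = 2.1e-24), Tnfaip3, a brake on NF-kB, changed by −1.09 ± 0.04 and Cxcl2, a neutrophil attractant, by −1.12 ± 0.07. Nos2, inducible nitric oxide synthase, fell from 40.2 ± 1.4 to 15 ± 0.321 CPM, and Irg1, which makes itaconate, changed by −2.89 ± 0.11. The list of classical macrophage activation went both ways (5 higher, 6 lower of 13, camera adjusted p = 0.63), with Fcgr1, an antibody receptor, up by 1.43 ± 0.04. Mitosis genes were lower in 33 of 37 cases (35 adjusted over the list alone) (median −0.43), with Mki67 from 385 ± 0.736 to 286 ± 2.04 CPM. Immediate early genes were lower in 19 of 22 cases and higher in 1 (median −0.66), with Egr1 at −1.69 ± 0.06, and chemokines lower in 7 of 10 and higher in 1 (median −0.56). In all 7646 of 14262 genes were called, 3632 higher and 4014 lower (47.5% higher), or 59.3% higher scaled by library size alone, and 531 moved at least 2-fold. Camera's adjusted p ran from 8e-121 for hypoxia and 9.3e-85 for stress to 9.3e-05 for chemokines. All but classical activation and S phase held with an estimated correlation, and other counts were the same adjusted over the list alone.

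With olaparib, fewer macrophage genes differed by partner. The interferon list was not called (12 higher, 3 lower of 46, camera adjusted p = 0.067), nor was the hypoxia list. Stress genes were higher in 22 of 28 cases (23 adjusted over the list alone) and lower in 2 (median 0.23), with Ddit3 at 0.64 ± 0.02. Sterol synthesis genes were lower in 20 of 24 cases (22 adjusted over the list alone) (median −0.30), with Sqle, squalene epoxidase, at −0.40 ± 0.03. S phase genes were lower in 31 of 37 cases (33 adjusted over the list alone) (median −0.30), with Mcm6, part of the replicative helicase, at −0.40 ± 0.03, and macrophage lineage genes in 15 of 25 with 5 higher (median −0.08), with Csf1r, a receptor for macrophage growth factors, at −0.36 ± 0.02. Mmp9, a matrix protease, fell from 48.2 ± 0.156 to 17.8 ± 0.634 CPM (−1.44 ± 0.04, adjusted p = 2.1e-31), Tnf changed by −0.47 ± 0.04 and Hpse, heparanase, by 0.98 ± 0.03. Altogether 5015 genes were called, 2504 higher and 2511 lower (49.9% higher), or 75.6% higher scaled by library size alone, and 153 moved at least 2-fold. The 4 lists passed camera at adjusted p between 4e-27 and 9.8e-09 and held with an estimated correlation.

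Olaparib against DMSO in macrophages asks how the drug in the well changed them. Opposite vector cells, all 37 mitosis genes were lower (median −0.46), with Mki67 from 385 ± 0.736 to 274 ± 2.79 CPM (−0.49 ± 0.02, adjusted p = 6e-29) and Prc1, which organizes the spindle midzone, at −0.56 ± 0.03. S phase genes were lower in 28 of 37 cases (30 adjusted over the list alone) (median −0.26), and homologous recombination genes in 31 of 49 (34 adjusted over the list alone) (median −0.20; 1 higher adjusted over the list alone). Stress genes were higher in 20 of 28 cases (21 adjusted over the list alone) and lower in 1 (median 0.24), with Hspa5 at 0.37 ± 0.01, and sterol synthesis genes in 17 of 24 (19 adjusted over the list alone) (median 0.17), with Sqle at 0.40 ± 0.03. Mmp9 rose from 23.4 ± 0.622 to 48.2 ± 0.156 CPM and Cd274 by 0.39 ± 0.04. In total 4057 genes were called, 1992 higher and 2065 lower (49.1% higher), or 14.7% higher scaled by library size alone, and 134 moved at least 2-fold. Yam1, chosen after its values were seen, took 4.34% to 4.61% of gene counts with olaparib here and 1.94% to 2.18% with DMSO. Reads in no gene were 21.02% to 21.51% with olaparib and 18.57% to 20.11% with DMSO. The 5 lists passed camera at adjusted p between 8.5e-64 and 1.7e-09 and held with an estimated correlation.

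Opposite F133V cells, olaparib moved macrophage genes further. Hypoxia and glycolysis genes were higher in 32 of 34 cases and lower in 1 (median 0.94), with Bnip3 from 111 ± 3.12 to 439 ± 2.46 CPM (1.99 ± 0.02, adjusted p = 6.8e-54), Slc2a1 at 1.34 ± 0.02 and Ndrg1 at 1.3 ± 0.01. Interferon genes were lower in 37 of 46 cases and higher in 3 (median −0.67), with Ifi44 from 59.9 ± 0.807 to 21.8 ± 1.28 CPM and Oas3 at −0.70 ± 0.03. Stress genes were lower in 22 of 28 cases and higher in 5 (median −0.44), with Pdia4 from 942 ± 6.05 to 474 ± 3.76 CPM. NF-kB genes were higher in 20 of 30 cases and lower in 3 (4 adjusted over the list alone; median 0.38): Nos2 rose from 15 ± 0.321 to 52.1 ± 1.71 CPM, Tnfaip3 by 1.23 ± 0.04, Cxcl2 by 1.43 ± 0.06 and Tnf by 0.37 ± 0.04. S phase genes were lower in 33 of 37 cases and higher in 1 (2 adjusted over the list alone; median −0.55), with Cdc6, a replication licensing factor, at −1.40 ± 0.06. Tnfrsf9, the costimulatory receptor 4-1BB, rose from 2.63 ± 0.137 to 28.8 ± 1.6 CPM, Pgf, placental growth factor, from 1.37 ± 0.157 to 16.5 ± 0.245, Hmox1, heme oxygenase, by 1.07 ± 0.02 and Cd274 by 0.68 ± 0.03. Altogether 8207 genes were called, 4069 higher and 4138 lower (49.6% higher), or 36.7% higher scaled by library size alone, and 617 moved at least 2-fold. The 5 lists passed camera at adjusted p between 6e-141 and 1.6e-04 and held with an estimated correlation.

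The interaction of partner genotype and olaparib in macrophages called 7037 genes, 3659 higher and 3378 lower with the F133V partner. Hypoxia genes had a positive interaction in 32 of 34 cases and negative in 1 (2 adjusted over the list alone; median 0.86), and NF-kB genes positive in 24 of 30 and negative in 3 (median 0.47). Interferon genes had a negative interaction in 33 of 46 cases (35 adjusted over the list alone) and positive in 3 (median −0.60), stress genes negative in 24 of 28 and positive in 3 (median −0.63) and sterol genes negative in 21 of 24 (median −0.48; 1 positive adjusted over the list alone). Bnip3 differed by 1.82 ± 0.03 (adjusted p = 4.1e-46), Abca1 by 2.10 ± 0.03, Tnfaip3 by 0.93 ± 0.06, Pdia4 by −1.37 ± 0.02 and Ifi44 by −1.77 ± 0.07. These 5 lists had camera adjusted p between 3.1e-103 and 2.5e-05 and held with an estimated correlation.

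**Figure D4:**
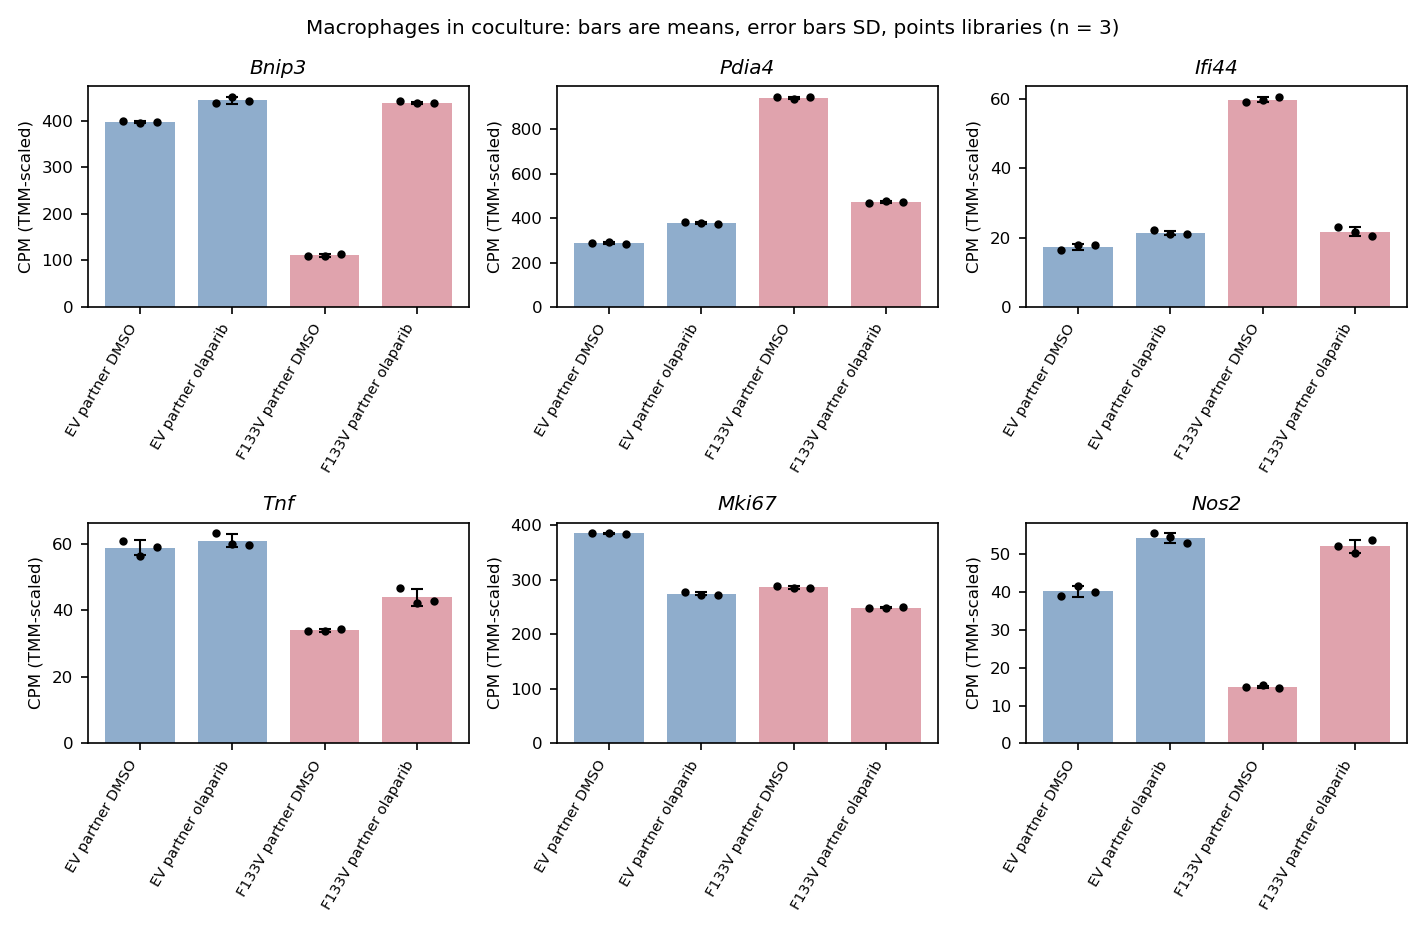
TMM-scaled CPM of 6 genes in the 4 groups of macrophages; bars are means, error bars SD and points the 3 libraries, with the vector partner in blue and the F133V partner in red. Bnip3 averages 111 opposite F133V cells with DMSO and 397 to 444 in the other 3 groups.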

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

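The tests of structural RNA, of vector cells in F133V wells, of single libraries and of protein-coding genes alone were chosen after the results were seen; the others were written before their results were seen. The 5 interactions drew attention because the difference between 2 groups' responses was itself tested and called many genes.

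In cancer cells grown alone, 3867 genes responded differently to olaparib in F133V than in vector cells, with Akr1b3 at −0.95, Egln3 at 0.99 and Bhlhe40 at 1.08. List medians were −0.17 for homologous recombination, −0.25 for mitosis, −0.39 for S phase and 0.13 for hypoxia. Of 30 splits of the 12 libraries, 2 called as many genes, so this count of splits does not exclude chance. The highest other split called 11323, several times the real count, which points to a structure of the samples: its contrast lined up 100% with genotype. It thus carries the genotype difference and gives no level for an absent interaction. Of the other splits, 13 were balanced on genotype, and the highest of them called 0 genes against 3867, although 13 are too few for a share under 0.05.

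In coculture 10751 genes differed in their response to olaparib. Akr1b3 stood at −3.39, Gclm at −3.38, Cenpf at 1.27 and Ddx58 at 1.27. List medians were 1.28 for interferon, 1.28 for sterol synthesis, 0.77 for hypoxia, 0.67 for mitosis, −0.54 for p53 targets and −0.88 for NRF2. The response to coculture with DMSO differed in 10008 genes, with Ddx58 at −1.84, Cebpd at −1.79, Csf1 at −1.44, Txnrd1 at 1.34 and Krt18 at 2.27, and with list medians of −1.21 for interferon, 0.44 for hypoxia, 0.73 for NRF2 and 0.57 for epithelial genes. Between coculture and monoculture, averaged over genotypes, the response to olaparib differed in 8957 genes: Gclm at −1.38, Ddx58 at 0.6, Col3a1 at 1.01, and list medians of 0.51 for interferon, 0.38 for sterol synthesis and −0.48 for NRF2. These averages describe neither genotype. In macrophages 7037 genes responded differently with the F133V partner. Ifi44 stood at −1.77, Pdia4 at −1.37, Tnfaip3 at 0.93, Bnip3 at 1.82 and Abca1 at 2.1, with list medians of −0.6 for interferon, 0.47 for NF-kB, −0.48 for sterol synthesis, −0.63 for stress and 0.86 for hypoxia.

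For these 4 interactions 1 of 30 splits, the real one, called as many. Other splits mix groups that differ in genotype or treatment, so they give no level for an absent interaction, and this count of splits does not decide about chance. The highest of the other splits called 9555 against 10751, 7760 against 10008, 4811 against 8957 and 2668 against 7037. Splits balanced on genotype numbered 15, 11, 5 and 15 in that order, and the highest of them called 9555, 514, 0 and 174. For each of the 12 comparisons of 2 groups, 10 splits are too few for a share under 0.05. The real split of F133V against vector cells called 10809 alone and 12686 in coculture, and the highest other 0 each. For olaparib the real counts were 4857 and 5772 alone in vector and F133V cells (highest other 1 and 66), and 3765 and 12185 in coculture (0 and 0). For coculture they were 6710 in vector and 11226 in F133V cells (0 and 1). In macrophages they were 7646 and 5015 for the partner with DMSO and olaparib (1 and 0), and 4057 and 8207 for olaparib opposite vector and F133V cells (0 and 0).

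F133V cells in coculture with DMSO lay far from F133V cells grown alone, at −102.6 to −101.9 on the first principal component against −49.9 to −49.4, while all vector libraries lay between 40.4 and 55.9. The structural RNA share was 1.11 times that of monoculture, far from the 5.52 between genotypes. This argues only against a difference in RNA quality or selection that changes structural RNA, and other such differences stay open. The mitochondrial share of gene counts was 2.14% to 2.29% in F133V monoculture with DMSO and 1.64% to 1.77% in coculture. In vector cells it was 2.44% to 2.65% and 2.38% to 2.49%. Gene length and GC trends are argued against, since 9963 genes were called for genotype by coculture with the trends removed, against 10008. Vector cells in these wells, or labels exchanged with vector libraries, would move the libraries toward the vector side and not away from it, so the median of 3.05% of the vector coculture level for 23 genes high in vector cells followed from the pattern and is no separate evidence (an exchange among F133V libraries was not tested). A response of F133V cells to macrophages may explain the distance, and it remains a hypothesis found and tested on the same data.

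In cancer cells, olaparib changed 12185 genes in F133V coculture and 3765 in vector coculture. A single library is argued against, since the lowest count with 1 library left out was 11793. With protein-coding genes only, 10506 genes were called. Structural RNA took just 409 ± 14 CPM of gene counts in F133V coculture with DMSO, too small a share to alter most calls by taking counts. That count thus followed from the size of the share and is no separate evidence. RNA quality or selection stays open, because structural RNA was 4.08 times higher with DMSO than with olaparib in F133V coculture and 1.15 times in vector coculture. A response of F133V cells to the drug may explain the count, and these values do not separate it from a difference in RNA that came with the treatment.

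Macrophage transcripts appeared in 2 of the 3 vector monoculture libraries with DMSO. Of 130 genes far higher in macrophages than in cancer cells, 88.5% were above the third library, where macrophage RNA or cells in these libraries predict nearly all. The share of macrophage RNA that each gene would need had quartiles of 0.0346%, 0.0619% and 0.086%, a ratio of 2.48 between the outer ones, under the limit of 3 that was predicted. A small carry-over of macrophages or their RNA is a candidate source that these values leave open, and the design gives no biological group to test against it.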

How the results depend on the processing

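Protein-coding genes only, the removal of 2 vector libraries and the removal of length and GC trends were chosen after seeing the data. Of 284 recomputed counts of called genes, 283 stayed within 1.5 times the reported one. The exception was olaparib in vector monoculture, at 2952 against 4857 without the 2 vector libraries with macrophage transcripts. That leaves 1 vector DMSO library, which is assumed to vary like the others, so fewer samples are part of the cause. With 1 library left out, that count ran from 4145 to 4281, F133V against vector monoculture from 10332 to 10462, olaparib in F133V coculture from 11793 to 11955 and the macrophage interaction from 6693 to 6904. Among 3006 recomputed values of named genes, 3004 kept their direction and their side of the threshold. Spop in F133V against vector monoculture was −0.01 and no longer called with length and GC trends removed. Parp1 with olaparib in F133V monoculture, not called, was 0.04 scaled by library size alone against −0.04; the cause was not tested.

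Of 812 recomputed list tests, 740 kept direction and call and 72 lost the call, 66 of them with an estimated correlation, 4 scaled by library size alone, 1 with RLE and 1 with a replicate block. Replicate numbers did not pair libraries: the mean correlation of residuals between libraries with the same number was 0 in cancer cells and 0.004 in macrophages. With a paired fit by replicate block, olaparib in vector monoculture called 4885 genes against 4857. By DESeq2 the macrophage comparisons called 3274 to 7485 genes. Libraries held 30292309 or more gene counts; what depth limits was not tested.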

Other observations

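The clock genes were not described above. Nr1d2, a nuclear receptor that represses clock genes, and Clock, which activates them, were both higher in F133V than in vector cells in coculture with DMSO, at 283 ± 10.3 against 69.7 ± 3.71 CPM and 475 ± 7.09 against 166 ± 4.13 CPM. The list of 15 clock genes went both ways in that comparison (8 higher and 7 lower, camera adjusted p = 0.22). With olaparib in F133V coculture Nr1d2 and Clock fell by 1.62 and 1.33 on the log2 scale. The list of 15 clock genes went both ways there (8 higher and 7 lower, camera adjusted p = 0.92). With olaparib in monoculture it was called in F133V cells (6 higher, or 7 adjusted over the list alone, and 4 lower, adjusted p = 1.6e-05, adjusted p = 0.0062 with an estimated correlation). In vector monoculture its adjusted p of 0.032 became 0.17 with an estimated correlation. In macrophages opposite F133V cells, 13 of 14 clock genes were higher with olaparib (median log2 fold change 0.58, adjusted p = 6.1e-09), with Nr1d2 up by 0.64 ± 0.03. With DMSO, 8 of 14 were lower opposite F133V than opposite vector cells and 1 was higher, with Bhlhe41 at −0.75 ± 0.02.

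SPOP presents proteins for degradation, so a change in a substrate's protein need not show in its transcript. Of 21 genes listed as SPOP substrates or partners, 16 were higher and 4 lower in F133V than in vector coculture with DMSO (camera adjusted p = 0.0016, adjusted p = 0.096 with an estimated correlation). Sqstm1, an autophagy receptor, stood at 4180 ± 89.3 against 1770 ± 4 CPM. With olaparib in F133V coculture 17 of the 21 were lower and 3 higher (adjusted p = 2.4e-04, adjusted p = 0.042 with an estimated correlation), with Brd2, a reader of acetylated histones, at −0.98 ± 0.02 and Sqstm1 at −0.85 ± 0.02. In monoculture the list was not called (11 higher, 6 lower, adjusted p = 0.21). Atp6v0d2, a proton pump subunit of osteoclasts, changed in macrophages by −0.59 ± 0.03 with the F133V partner and by 1.3 ± 0.03 with olaparib opposite F133V cells.

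A hypothesis written before its result was that both cell types of a well share a condition, such as nutrients or oxygen, that would move the same genes the same way. The genotype by olaparib interaction was compared between the cancer cells and the macrophages of the cocultures, which share no libraries. Across 12966 genes tested in both, which are not independent replicates, Pearson's r was −0.002 and Spearman's rho −0.009. Of 5153 genes called in both, 2435 (47.3%) changed in the same direction, and the margins alone predict 4645 called in both. For a shared condition that moves different genes in each cell type, the correlation cannot tell. Across all genes the values argue only against a main source of both interactions that moves the same genes the same way. The hypoxia list differs from this: its interaction was positive in 27 of 34 cases in cancer cells (median 0.77) and in 32 of 34 in macrophages (median 0.86). With DMSO these genes were lower with F133V in both, at medians of −0.53 and −0.81. In cancer cells, however, 33 of 34 were lower with F133V in monoculture, without macrophages (median −0.92), and coculture raised 29 of 34 in F133V cells (median 0.58). The lower level in F133V cancer cells thus did not need a coculture. For the hypoxia genes of macrophages and for the interaction in cancer cells, a condition of the well such as oxygen or nutrients stays open, since neither was measured.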
